A study of Mus musculus with 88 samples.

How the data were processed

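On each array, RNA of RAW 264.7 macrophages exposed for 1, 2 or 4 h to LPS, to ISO, to PGE2 or to LPS with either of the other ligands was compared with RNA of cells kept in medium for the same time. Doses per the labels were 100 ng/ml LPS, 50 nM ISO and 10 µM PGE2. For LPS alone the labels also name 100 pM lipid binding protein. They do not name it for the combinations. The arrays were 2-colour custom Agilent oligonucleotide arrays labelled with Cy3 and Cy5, per the series design text. Groups, sets and dye orientation were taken from the titles, channel sources and dyes in the labels. This gave 44 dye-swap pairs of 2 arrays in 15 groups, with 3 sets per group and 2 for PGE2 at 1 h.

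The authors deposited 1 value table with a log2 ratio per probe and array. Image analysis, normalization and filters are not given in the sources used here. The scale was read from the values: the largest absolute value, 6.64, is log2 of 100, and 17 values lay at that limit. Scale is thus inferred, and direction stays unstated in the sources. Per the values as deposited, the median was 0 in all 88 columns. The share of probes at exactly 0 was 10.95 to 45.67% per array (median 28.3%), or 1782 to 7435 probes (median 4608), and these zeros hold the column medians at 0. What an exact 0 stands for is not given in the sources used here, and a probe is called measured on an array where its value is other than 0. The median of the values other than 0 lay between −0.029 and 0.032. How the authors centred the values therefore also stays unknown. A mean that includes zeros is drawn toward 0. No intensities were part of the table, so the signal behind each ratio is unknown here.

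Ratios were first read as Cy5 over Cy3, and arrays with the treated RNA in Cy3 had their sign turned. To test this reading, 20 genes known to be induced by LPS were listed, of which 18 were measured. Their median was above 0 on 18 of 18 arrays with LPS alone, from 0.824 to 2.57. The direction was then kept for all arrays and called likely. After turning, the 2 arrays of a pair had r of 0.204 to 0.85 across probes in the 27 pairs with LPS and of −0.585 to 0.321 in the 17 pairs without LPS, of which 10 lay below 0. The 2 arrays of a pair hold the same RNAs, so they were averaged to 1 value. A dye effect cancels in that mean where both arrays hold a value other than 0. Where only 1 of them is at 0, part of a dye effect may stay in the mean.

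The table held 16281 probes. The platform annotation listed 13790 of them, 13738 with 1 gene symbol and 52 with several, and left 2491 unlisted. Symbols were updated through Entrez identifiers with a RefSeq table of assembly GRCm38.p6, in which 13694 of the probes with 1 symbol were found, and the other symbols were kept. Of the probes with 1 gene, 478 were at 0 on every array and were left out, as were probes with several genes or none listed. The remaining 13260 probes were averaged to 10518 genes, 2452 of them with several probes. Where the probes of a named gene disagree in sign or size, their values are given. No coordinates are printed.

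Tests were run in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. The 44 pair means were fitted in 1 model with a mean for each of the 15 groups (lmFit), so that all groups share 1 estimate of the spread, with eBayes without trend (29 residual degrees of freedom, 2.678 prior degrees of freedom). Adjusted p is from the Benjamini-Hochberg method over all genes of a comparison, and 0.05 was the threshold. The comparisons were each treatment with medium at each time, each combination with LPS alone, ISO with PGE2, the departure of each combination from the sum of its single treatments (F test over the 3 times), and the difference of each response between times (F test). The ratio against 0 is the test against medium. Tests of single contrasts are two-sided. Sets are the replicates, and SD is the spread between set means.

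In all, 23 gene lists were fixed: cytokines and chemokines, NF-kB subunits and feedback regulators, interferon-stimulated genes, cAMP and CREB targets, serum-responsive genes, receptors and enzymes of the cAMP pathway, regulators of G protein signalling and other receptors of that class, eicosanoid enzymes, macrophage receptors and identity genes, alternative activation, antigen presentation, adhesion and matrix, apoptosis and survival, G1 and S phase, G2 and M phase, glycolysis and hypoxia, oxidative stress, heat shock and unfolded protein response, sterol synthesis, LXR targets, osteoclast genes, markers of other cell types, and reference genes. They were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over all lists and comparisons of the same kind. Where no p with an estimated correlation is given beside a camera call without a block, the call also held with it.

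Genes were named by a rule: for a single treatment at a time, the 8 highest and 5 lowest among genes past the threshold with the same sign in every set; for a combination against LPS alone, the 6 highest and 6 lowest past the threshold with set values that do not overlap; for ISO against PGE2 the 3 highest and 3 lowest likewise; for each departure from additivity the 5 with the smallest p; up to 4 members of each described list; and 25 genes always considered. Members of the first 3 parts could be left out, and not always in order of size. The comparisons, lists, naming rule and the first group of alternatives below were fixed before the data were examined.

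Whether set numbers pair the samples was checked from the deviations of sets from their group means. Across genes, 84 of 86 pairs of sets with the same number at the same time had r above 0.1 (0.028 to 0.766, median 0.361). The median for different numbers was −0.184. Deviations within a group sum to 0, so this negative value follows from the positive one and is no separate evidence. All 18 pairs of a combination set with an LPS set (0.197 to 0.6) and all 8 pairs of an ISO with a PGE2 set (0.186 to 0.661) lay above 0.1. The numbers were therefore taken to pair samples in those comparisons, and the value with the set number as a block is given where it changes a call or moves a count by over 1.5 times. The block was fixed within time for comparisons between treatments (23 residual degrees of freedom) and random for those with medium and between times (correlation 0.317).

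The first alternatives were centring each array, only the groups of a comparison in the fit, leaving out each set, only probes measured on all 88 arrays, the set number as a block, robust eBayes, each probe on its own, all 88 arrays with a dye term, and zeros as missing. Added after the data were seen were centring on the median of values other than 0, the unlisted probes and those with several genes included, and only genes measured on at least 44 arrays. Because ISO and PGE2 were compared with medium of the same times, unchanged groups with shared controls were simulated 100 times and pairs of different set numbers were used alone. The fits were tested on simulated data with 200 of 10518 genes changed. For ISO at 4 h, 92.5% of genes changed by 0.5 log2 and 98.5% of those changed by 1 were recovered, with 11 false calls. For LPS plus ISO against LPS alone at 4 h the shares were 62.7% and 97%, with 3 false calls, and with the set number as a block 74.6% and 98.5%, with 11 false calls among 193 calls. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.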

Results

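Gene expression was measured in RAW 264.7 cells, a mouse macrophage-like cell line, after 1, 2 or 4 h with 5 treatments. Lipopolysaccharide (LPS, 100 ng/ml), a component of the outer membrane of Gram-negative bacteria, activates Toll-like receptor signalling. Isoproterenol (ISO, 50 nM) is a beta-adrenergic agonist and prostaglandin E2 (PGE2, 10 µM) a lipid mediator, and both can raise cyclic AMP in macrophages. Each ligand was given alone, and ISO and PGE2 were also given together with LPS. RNA of treated cells was compared on 2-colour oligonucleotide arrays with RNA of cells kept in medium for the same time, and every comparison was hybridised with both dye orientations. The 88 arrays formed 44 dye-swap pairs in 15 groups. Each group held 3 sets of 2 arrays, except PGE2 at 1 h, which held 2 sets. The number of arrays limits the precision. The labels do not say whether the sets came from separate cultures, so p-values measure only the spread between sets, which may be technical. The deposited values did not state which channel was the numerator. The direction used here, treated over medium, is likely rather than known. Its basis is that the known LPS target genes fixed for this purpose had a positive median on 18 of 18 arrays with LPS alone once ratios were turned by the dye labels. All signed values below are log2 ratios of treated over medium cells, as the mean of the sets.

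After 1 h with LPS, immediate early and inflammatory genes rose. Egr1, a zinc-finger transcription factor induced by growth and stress signals, was 34.1-fold higher than in medium (log2 ratio 5.09 ± 0.77, SD, n = 3), its relative Egr2 was 23.4-fold higher and Phlda1 was 23-fold higher. Btg2, an antiproliferative gene, was 17.3-fold higher, Nfkbiz, a nuclear regulator of the IkB family, 12.8-fold, and Dusp1, a phosphatase that dampens MAP kinase signalling, 12.7-fold. Tnf, which encodes the cytokine tumour necrosis factor, was 12.4-fold higher (3.63 ± 0.084, SD, n = 3), and Zfp36, whose product destabilises cytokine mRNAs, 11.2-fold. Txnip, which encodes a thioredoxin-binding protein, was 4.34-fold lower (−2.12 ± 0.65, SD, n = 3), followed by Sfi1 at 2.99-fold, Agfg2 at 2.96-fold and the transcript 4930402H24Rik at 2.67-fold. The adjusted p in limma was 4.77e-09 for Egr1, 9.75e-17 for Tnf, 4.77e-09 for Txnip and 0.000156 for Sfi1.

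Of 10518 genes, 997 passed the threshold after 1 h with LPS, 488 higher and 509 lower, and 92 of these were at least 2-fold higher and 17 at least 2-fold lower. Without set 1 the count was 393. Of 26 measured cytokines and chemokines, 13 rose (14 adjusted over the list alone, camera adjusted p = 1.28e-12). Il1b was 7.40-fold higher and Cxcl10, an interferon-induced chemokine, 5.74-fold higher. Of 21 NF-kB subunits and feedback regulators, 15 rose (20 adjusted over the list alone, camera adjusted p = 1.28e-33), among them Ier3 at 9.26-fold. Of 25 serum-responsive immediate early genes, 15 rose (17 adjusted over the list alone, camera adjusted p = 3e-23). Of 28 cAMP and CREB target genes, 11 rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 3.89e-07). In that list Nr4a1, an orphan nuclear receptor, was 2.70-fold higher and Rgs2, a regulator of G protein signalling, was 2.23-fold lower. Of 19 heat shock and unfolded protein response genes, 10 rose (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.05e-05), including Ddit3 at 2.15-fold and the endoplasmic reticulum chaperone Dnajb9 at 2.10-fold. Of 41 interferon-stimulated genes, 6 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.0338). That call was lost at adjusted p = 0.694 with an estimated correlation.

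After 2 h with LPS, cytokine genes stood among the most raised. Il1b, which encodes interleukin 1 beta, was 24.9-fold higher than in medium (4.64 ± 0.50, SD, n = 3) and Il1a 12.5-fold higher. Phlda1 was 26.5-fold higher, Acod1, the enzyme that makes itaconate, 24.5-fold and Nfkbiz 14.6-fold. Cd83, an activation marker of antigen-presenting cells, was 12.6-fold higher, Ifnb1, which encodes interferon beta, 11.9-fold (3.57 ± 1.23, SD, n = 3) and Tnf 11.8-fold. Ptgs2, the inducible cyclooxygenase, was 5.85-fold higher and Il10, an anti-inflammatory cytokine, 5.81-fold higher. Txnip was 4.04-fold lower (−2.01 ± 0.13, SD, n = 3) and Lrrc17, which encodes a secreted leucine-rich protein, 3.39-fold lower. The adjusted p in limma was 8.3e-12 for Il1b, 7.27e-05 for Ifnb1 and 2.43e-05 for Ptgs2.

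LPS changed 1671 genes at 2 h, 934 higher and 737 lower, and the count was 1077 without set 1 and 1091 without set 3. Of the 26 cytokines and chemokines, 18 rose (18 adjusted over the list alone, camera adjusted p = 6.27e-17), and of the 21 NF-kB subunits and feedback regulators, 20 rose (20 adjusted over the list alone, camera adjusted p = 9.75e-35). Of 41 interferon-stimulated genes, 22 rose (25 adjusted over the list alone, camera adjusted p = 8.98e-14). The latter gave adjusted p = 0.0942 with an estimated correlation. Of 24 G2 and M phase genes, 8 fell (10 adjusted over the list alone, camera adjusted p = 5.22e-06). The mitotic kinase gene Ttk had a log2 ratio of −0.43 ± 0.17 (SD, n = 3) and the spindle motor gene Kif11 one of −0.36 ± 0.066. Of 23 apoptosis and survival genes, 13 rose and 3 fell (13 and 5 adjusted over the list alone, camera adjusted p = 3.92e-07), with Traf1, a signalling adaptor of tumour necrosis factor receptors, at 8.96-fold and the growth arrest gene Gadd45a at 7.41-fold. Of 19 antigen presentation genes, 6 rose (8 adjusted over the list alone, camera adjusted p = 0.000994), the largest change being in the co-stimulatory receptor gene Cd40 at 6.50-fold.

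After 4 h with LPS, interferon-stimulated genes stood among the most raised. Gbp2, an interferon-induced GTPase, was 31.6-fold higher (4.98 ± 0.37, SD, n = 3), Cmpk2 26.3-fold and Ifit3, an antiviral RNA-binding gene, 25-fold. Il1b was 37.3-fold higher (5.22 ± 0.61, SD, n = 3), the acute-phase gene Saa3 30.8-fold, Cd40 26.8-fold, Ifnb1 26.4-fold and Il6 24.9-fold (4.64 ± 1.64, SD, n = 3). On 1 of the 6 arrays the 3 Il1b probes stood at the deposited upper limit of 100-fold, so its mean is a lower bound. Il6 was listed at 0 on 1 of 6 arrays. Among annotated genes the largest fall was in Pax6, a developmental transcription factor, at 5.66-fold (−2.50 ± 0.30, SD, n = 3), followed by Id2 at 4.26-fold, the cohesion gene Esco2 at 3.98-fold, Angpt2 at 3.90-fold and the iron exporter gene Slc40a1 at 3.89-fold. The adjusted p in limma was 1.5e-20 for Gbp2, 4.63e-14 for Il1b, 2.02e-10 for Il6 and 4e-13 for Pax6.

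LPS changed 3228 genes at 4 h, 30.7% of those tested, with 1504 higher and 1724 lower, and 374 at least 2-fold higher and 119 at least 2-fold lower. Of 41 interferon-stimulated genes, 39 rose (39 adjusted over the list alone, camera adjusted p = 9.8e-43), with a median log2 ratio of 2.69. Of 26 cytokines and chemokines, 21 rose (21 adjusted over the list alone, camera adjusted p = 2.02e-15), and of 21 NF-kB subunits and feedback regulators, 19 rose (19 adjusted over the list alone, camera adjusted p = 4.15e-17). Csf2, which encodes a myeloid growth factor, was 13-fold higher, Il10 9.22-fold, and Nfkbia, the feedback inhibitor of NF-kB, 3.82-fold. Nos2, the inducible nitric oxide synthase, was 3.92-fold higher at 4 h (1.97 ± 0.53, SD, n = 3), while its log2 ratios at 1 and 2 h were 0.04 and 0.17 and did not pass. Of 23 G1 and S phase genes, 19 fell and 1 rose (19 and 1 adjusted over the list alone, camera adjusted p = 2.49e-10). Cdc6, which licenses replication origins, was 3.24-fold lower, the histone mRNA-binding gene Slbp 2.39-fold, and Rrm2, a subunit of ribonucleotide reductase, 2.05-fold. Of 24 G2 and M phase genes, 17 fell (18 adjusted over the list alone, camera adjusted p = 4.4e-08), with the proliferation marker Mki67 1.82-fold lower and the cyclin gene Ccna2 1.73-fold lower.

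Further lists moved at 4 h with LPS. Of 34 macrophage surface receptor and identity genes, 19 rose and 4 fell (19 and 4 adjusted over the list alone, camera adjusted p = 6.64e-08), with the formyl peptide receptor gene Fpr2 at 8.58-fold, Tlr3 at 6.71-fold and Clec4e, a C-type lectin receptor, at 5.18-fold. Of 19 antigen presentation genes, 13 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 9.95e-08), including the peptide transporter gene Tap1 at 3.92-fold. Of 20 adhesion and matrix genes, 12 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 3.54e-05), led by the matrix protein gene Tnc with a log2 ratio of 3.51. Of 24 regulators of G protein signalling and other receptors of that class, 12 rose and 4 fell (12 and 4 adjusted over the list alone, camera adjusted p = 0.000799), with Rgs16 at 9.10-fold. Of 21 oxidative stress genes, 8 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.00657). The metal-binding gene Mt2 was 3.00-fold higher and Gclc, which catalyses the limiting step of glutathione synthesis, was 2.62-fold lower. Of 25 serum-responsive genes, 13 rose and 1 fell (13 and 2 adjusted over the list alone, camera adjusted p = 2.48e-05). Of 23 apoptosis and survival genes, 14 rose and 3 fell (14 and 4 adjusted over the list alone, camera adjusted p = 4.93e-06), led by the death receptor gene Fas at 17.0-fold. That call gave adjusted p = 0.0519 with an estimated correlation. Of 18 glycolysis and hypoxia genes, 6 rose (7 adjusted over the list alone, camera adjusted p = 0.00711), among them the glucose transporter gene Slc2a1 at 2.01-fold and the hexokinase gene Hk2 at 1.92-fold, with adjusted p = 0.189 with an estimated correlation. Of 20 alternative activation genes, 9 rose and 3 fell (9 and 3 adjusted over the list alone, camera adjusted p = 0.0223), again with adjusted p = 0.189 with an estimated correlation.

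The remaining 9 lists did not pass camera's test at 4 h with LPS. The 28 cAMP and CREB target genes had 6 higher and 4 lower members (6 and 5 adjusted over the list alone, camera adjusted p = 0.793), and the 19 heat shock genes 2 higher and 3 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.96), with Dnajb9 now 2.20-fold lower. The 22 receptors and enzymes of the cAMP pathway had 2 higher and 4 lower (2 and 4 adjusted over the list alone, camera adjusted p = 0.97), and the 16 eicosanoid enzymes 4 higher and 5 lower (4 and 5 adjusted over the list alone, camera adjusted p = 0.994). The 11 sterol genes had 4 higher and 1 lower (4 and 2 adjusted over the list alone, camera adjusted p = 0.86), the 12 LXR targets 2 higher and 4 lower (2 and 4 adjusted over the list alone, camera adjusted p = 0.514), and the 9 osteoclast genes 4 higher and 1 lower (4 and 2 adjusted over the list alone, camera adjusted p = 0.204). Of 22 markers of other cell types 0 passed limma's threshold and 1 had an unadjusted p under 0.05, with the list at camera adjusted p = 0.649. Of 19 reference genes, 1 was higher and 2 were lower (1 and 2 adjusted over the list alone, camera adjusted p = 0.951).

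With only the group itself in limma's fit, the LPS counts were 5 at 1 h, 131 at 2 h and 1461 at 4 h. The LPS response differed between times for 1943 genes (limma's F test over the 3 times), and for 1053 with only the LPS groups in the fit. Of these, 201 had their largest absolute log2 ratio at 1 h, 172 at 2 h and 1570 at 4 h. Il6 had log2 ratios of 0.47 at 1 h, 2.12 at 2 h and 4.64 at 4 h, and the 2 h value passed at adjusted p = 0.000577 but not without set 3 (adjusted p = 0.0533). Dusp1 had log2 ratios of 3.66, 2.38 and 0.47 at the same times. Nr4a1 had 1.44, 0.34 and −0.81, of which the 1 h value passed, and the 4 h value passed only with the set number as a block (adjusted p = 0.0546, and 0.0155 with the block). Tnf had 3.63, 3.56 and 3.42, all past the threshold. Il12b had log2 ratios of 0.18, −0.05 and 0.11 and Socs3, a feedback inhibitor of cytokine signalling, of 0.02, 0.05 and 0.09, and none of these passed. Ccl3, a macrophage chemokine gene, was 2.28-fold higher at 1 h (adjusted p = 0.00387, and 0.101 without set 3), but it was listed at 0 on 5 of 6 arrays at 2 h and on 6 of 6 at 4 h.

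**Figure D1:**
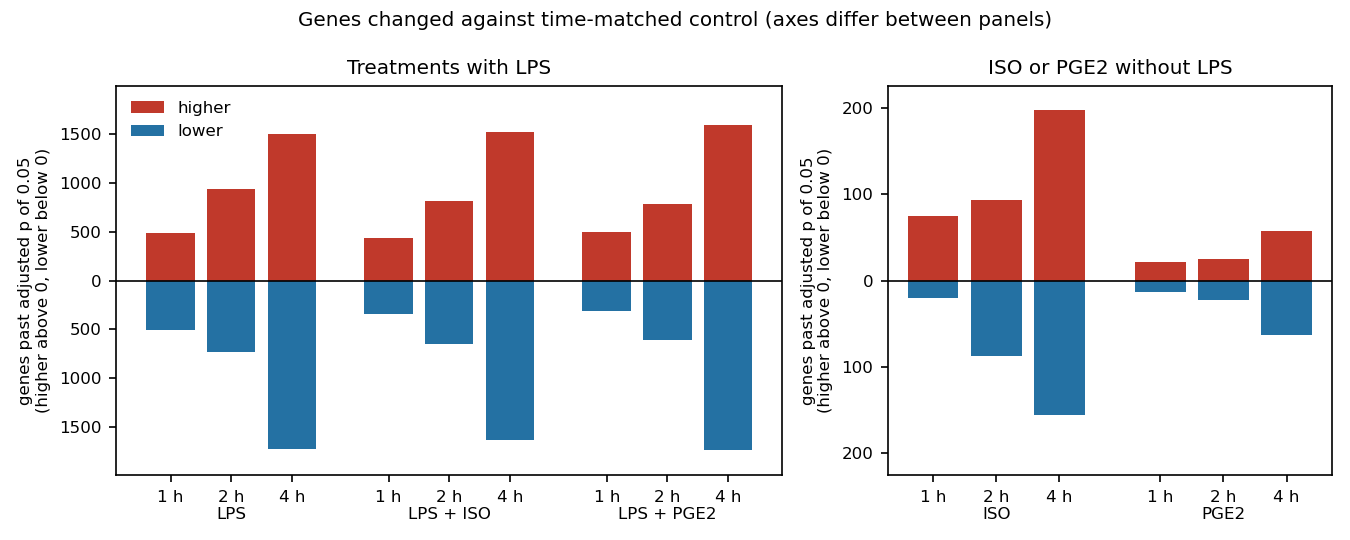
Number of genes past an adjusted p of 0.05 in limma against medium, higher and lower, for each treatment at 1, 2 and 4 h, with the treatments that include LPS and those without it on separate axes. The bars run from 488 higher and 509 lower at 1 h to 1504 and 1724 at 4 h for LPS alone, and ISO reached 197 and 156 at 4 h.

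After 1 h with ISO alone, targets of cAMP signalling rose. Nr4a1 was 5.39-fold higher than in medium (2.43 ± 0.33, SD, n = 3, adjusted p = 2.05e-05 in limma), Il1b 3.78-fold, Hilpda, which encodes a lipid droplet protein, 3.50-fold and Pde4b, a cAMP-degrading phosphodiesterase, 3.42-fold. Dusp1 was 3.27-fold higher and Ier3 2.98-fold. Rgs1, a regulator of G protein signalling, was 4.05-fold lower, the polo-like kinase gene Plk2 3.29-fold lower (−1.72 ± 0.76, SD, n = 3), Rgs2 2.65-fold lower and Ptger4, which encodes the EP4 receptor for PGE2, 2.33-fold lower (−1.22 ± 0.35, SD, n = 3, adjusted p = 1.01e-06). Tnf, at −0.16 ± 0.64, did not pass. Without set 3 the calls of Il1b (adjusted p = 0.0808), Pde4b (adjusted p = 0.067) and Rgs1 (adjusted p = 0.0848) were lost.

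ISO changed 95 genes at 1 h, 75 higher and 20 lower, and 56 without set 2. Of 28 cAMP and CREB target genes, 6 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 7.95e-09), and the single member that fell was Rgs2. Nr4a2, a relative of Nr4a1, was 2.75-fold higher as the mean of probes at 0.30 and 2.62, and Cebpb, a transcription factor of myeloid cells, was 2.04-fold higher. Of 21 NF-kB subunits and feedback regulators, 3 rose (5 adjusted over the list alone, camera adjusted p = 2.32e-06), with adjusted p = 0.153 with an estimated correlation. Of 25 serum-responsive genes, 3 rose (5 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.023), with adjusted p = 0.301 with an estimated correlation. Of 26 cytokines and chemokines only Il1b passed (adjusted p = 0.0808 without set 3), and the list as a whole did not pass (camera adjusted p = 0.957). Vegfa, which encodes an angiogenic growth factor, was 1.92-fold higher and Tgm2, a transglutaminase, 2.30-fold higher.

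After 2 h with ISO, Edil3, which encodes an integrin-binding matrix protein, was 4.76-fold higher (2.25 ± 1.17, SD, n = 3), Tgm2 3.33-fold (1.73 ± 0.30, SD, n = 3, adjusted p = 2.62e-08 in limma), Pde4b 3.06-fold and Cytip, a cytohesin-binding protein gene, 3.05-fold. Rgs1 was 5.76-fold lower (−2.53 ± 0.31, SD, n = 3), the stress transcription factor gene Atf3 4.38-fold, Rgs2 3.44-fold and Plk2 3.37-fold. Ptger4 was 2.40-fold lower. Of 28 cAMP and CREB target genes, 7 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.00438), with adjusted p = 0.189 with an estimated correlation. Of 21 NF-kB subunits and feedback regulators, 3 rose (5 adjusted over the list alone, camera adjusted p = 9.9e-06), also with adjusted p = 0.189 with an estimated correlation. Among them Nfkbie, an inhibitor of NF-kB, was 2.25-fold higher. ISO changed 180 genes at 2 h, 93 higher and 87 lower, with 92 without set 1 and 110 without set 2. Without set 2 the call of Pde4b was lost (adjusted p = 0.074).

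After 4 h with ISO, Tgm2 was 4.04-fold higher (2.01 ± 0.41, SD, n = 3), and Clec4n, which encodes the pattern recognition receptor Dectin-2, 2.84-fold (1.5 ± 0.58, SD, n = 3, adjusted p = 9.86e-09 in limma, listed at 0 on 1 of 6 arrays). Cytip was 2.25-fold higher, Clec4e 2.24-fold, Acod1 2.19-fold and Clec4a2 2.14-fold. Hdac9, a histone deacetylase, was 2.40-fold lower (−1.26 ± 0.15, SD, n = 3). Of 34 macrophage surface receptor and identity genes, 8 rose (11 higher and 3 lower adjusted over the list alone, camera adjusted p = 1.82e-05), among them C5ar1, which encodes the complement C5a receptor. C5ar1 had a mean log2 ratio of 0.95 ± 0.26 (SD, n = 3) from probes at −0.02 and 1.91, so the gene mean stands for only 1 of its probes. Pparg, a lipid-sensing nuclear receptor of alternatively activated macrophages, was 1.62-fold lower, and the growth factor gene Igf1 1.45-fold lower. Of 24 G2 and M phase genes, 3 rose (8 adjusted over the list alone, 5 with the set number as a random block, camera adjusted p = 2.16e-06). Of 21 NF-kB subunits and feedback regulators, 2 rose (2 adjusted over the list alone, camera adjusted p = 0.0338), with adjusted p = 0.573 with an estimated correlation. ISO changed 353 genes at 4 h, 197 higher and 156 lower, and 211 without set 3. The response differed between times for 62 genes, with the largest absolute value at 1 h for 10, at 2 h for 17 and at 4 h for 35. That count was 27 without set 2 at 1 h, 41 without set 2 at 2 h, 19 without set 1 at 4 h and 26 without set 3 at 4 h. With only the group itself in limma's fit, 0 genes passed with ISO at 1, 2 and 4 h (806, 1389 and 1340 at an unadjusted p under 0.05), whereas the 88 single arrays with a dye term gave 290, 352 and 598.

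After 1 h with PGE2 alone, Plk2 was 3.68-fold lower than in medium (−1.88 ± 0.36, SD, n = 2, adjusted p = 0.000185 in limma) and Ptger4, the gene of its own EP4 receptor, 2.48-fold lower (−1.31 ± 0.020, SD, n = 2, adjusted p = 3.75e-05). Rgs1 was 4.12-fold lower and Rgs2 3.25-fold lower. Pde4b was 3.36-fold higher, Hilpda 2.88-fold and Ier3 2.46-fold. Nr4a1, at 1.67 ± 0.24 (SD, n = 2), did not pass (adjusted p = 0.0536) but did with the set number as a block (adjusted p = 0.00279). Of 28 cAMP and CREB target genes, 3 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 1.82e-05), and of 21 NF-kB subunits and feedback regulators, 1 rose (2 adjusted over the list alone, 2 with the block, camera adjusted p = 0.018). The NF-kB list gave adjusted p = 0.522 with an estimated correlation. PGE2 changed 34 genes, 21 higher and 13 lower, 15 without set 2, and 78 with the set number as a block, 41 higher and 37 lower. Without set 1 and without set 2 in turn, the adjusted p was 0.277 and 0.245 for Pde4b, 0.543 and 0.166 for Hilpda, 0.131 and 0.27 for Rgs1, and 0.109 and 0.0973 for Rgs2, and Ier3 was lost without set 1 (adjusted p = 0.179).

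After 2 h with PGE2, Edil3 was 3.2-fold higher (1.68 ± 1.14, SD, n = 3), Tgm2 2.63-fold (1.39 ± 0.37, SD, n = 3, adjusted p = 6e-06 in limma) and Cytip 2.16-fold. Rgs1 was 3.62-fold lower, Atf3 3.12-fold, Rgs2 2.95-fold (−1.56 ± 0.36, SD, n = 3), Plk2 2.62-fold and Ptger4 2.12-fold. Csf2rb2, a cytokine receptor subunit gene, was 1.93-fold higher and Cnnm2, which encodes a magnesium-related membrane protein, 1.57-fold. Of 28 cAMP and CREB target genes, 1 rose and 1 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.0203), with adjusted p = 0.286 with an estimated correlation. Of 21 NF-kB subunits and feedback regulators, 1 rose (2 adjusted over the list alone, camera adjusted p = 0.000801), with adjusted p = 0.331 with an estimated correlation. PGE2 changed 48 genes at 2 h, 25 higher and 23 lower, with 28 without set 1 and 23 without set 3. Edil3 was lost without set 3 (adjusted p = 0.0959), Rgs1 without set 2 (adjusted p = 0.215) and without set 3 (adjusted p = 0.238), and Atf3 without sets 1, 2 and 3 in turn (adjusted p = 0.14, 0.219 and 0.308).

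After 4 h with PGE2, Tgm2 was 3.6-fold higher (1.85 ± 0.25, SD, n = 3, adjusted p = 1.61e-08 in limma) and Clec4n 2.86-fold higher (1.52 ± 0.32, SD, n = 3), with Acod1 at 1.93-fold and Clec4e at 1.88-fold. Lrrc17 was 2.90-fold lower (−1.53 ± 0.062, SD, n = 3), Hdac9 2.09-fold and Kitl, which encodes stem cell factor, 2.09-fold. Of 34 macrophage surface receptor and identity genes, 4 rose (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.06e-05). Pparg was 1.61-fold lower. Of 21 oxidative stress genes, 1 rose (4 adjusted over the list alone, camera adjusted p = 0.00117), which was Acod1. Of the 24 G2 and M phase genes 0 passed limma's threshold and 5 had an unadjusted p under 0.05, while the list was shifted upward at camera adjusted p = 3.75e-05 and at adjusted p = 0.0729 with an estimated correlation. PGE2 changed 120 genes at 4 h, 57 higher and 63 lower, with 68 without set 1, 42 without set 2 and 35 without set 3. Acod1 was lost without sets 1, 2 and 3 in turn (adjusted p = 0.159, 0.216 and 0.305) and Hdac9 without set 2 (adjusted p = 0.0542). The PGE2 response differed between times for 1 gene (19 with the set number as a random block), with 0 without set 2 or set 3 at 4 h and 9 without set 1 at 1 h. With only the group itself in limma's fit, 0 genes passed with PGE2 at 1, 2 and 4 h (460, 1031 and 1925 at an unadjusted p under 0.05), whereas the 88 single arrays with a dye term gave 165, 134 and 335.

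**Figure D2:**
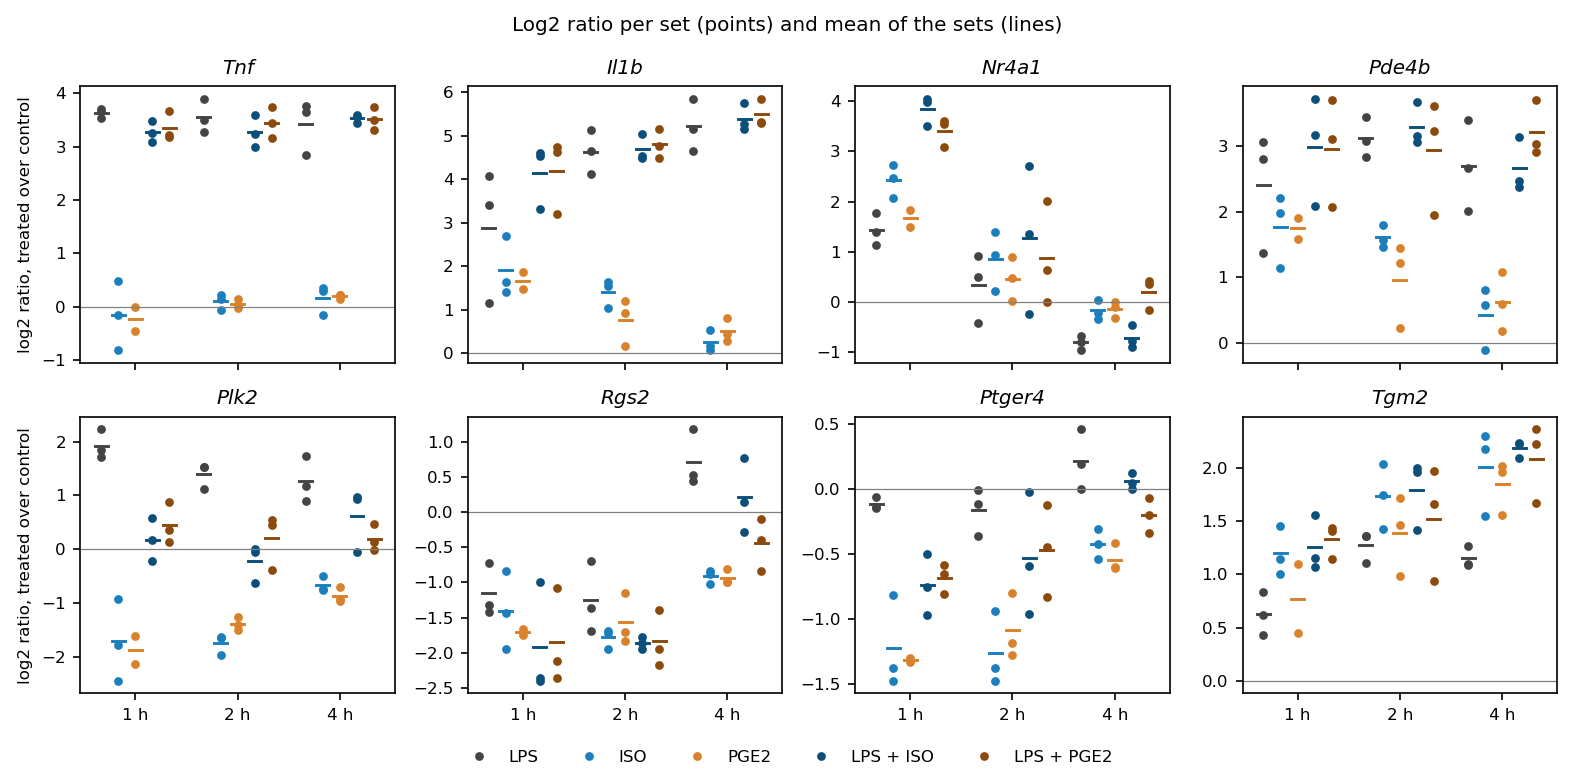
Log2 ratio of treated over medium cells at 1, 2 and 4 h for 8 genes, with points for the sets and lines for their means. Tnf stays between 3.42 and 3.63 with LPS alone and near 0 with ISO or PGE2 alone, Nr4a1 reaches 3.85 with LPS plus ISO at 1 h, and Tgm2 reaches 2.01 with ISO and 1.85 with PGE2 at 4 h.

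The responses to ISO and PGE2 were then compared directly. The genes that both lowered included Rgs2, Plk2 and Ptger4 at 2 h, and those that both raised included Tgm2 and Cytip at 2 h and Clec4n and Clec4e at 4 h. Between them 17 genes were called higher with both ligands at 1 h, 22 at 2 h and 52 at 4 h, where independent lists would share 0.15, 0.221 and 1.07, and 7, 21 and 51 were called lower with both, where independent lists would share 0.0247, 0.19 and 0.934. None was called in opposite directions. Controls shared by both ligands can also raise these overlaps, and no overlap was simulated with them. Pearson's r of the 2 sets of log2 ratios across genes, which are not independent replicates, was 0.665 at 1 h, 0.667 at 2 h and 0.694 at 4 h, and Spearman's rho 0.524, 0.338 and 0.54. Both ligands were compared with medium of the same times, and unchanged groups simulated with shared controls gave a mean r of 0.465, 0.293 and 0.331. The covariance was 0.016, 0.0119 and 0.0141 against simulated means of 0.00586, 0.00301 and 0.00341. Over sets of different number r was 0.411, 0.559 and 0.574. The simulated r covers all pairs of sets, so it is not a like measure for the r over sets of different number. Part of the likeness may come from shared control RNA.

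Tests of the difference between ISO and PGE2 in limma called 0 genes at 1, 2 and 4 h, with 233, 259 and 408 genes at an unadjusted p under 0.05, where 526 would be reached by chance. With the set number as a block, 0, 0 and 1 gene passed, the last being Npy5r, a neuropeptide Y receptor gene that was lower with ISO than with PGE2 at 4 h (difference −0.41, adjusted p = 0.193 and 0.0361 with the block). Without single sets the count reached 8 without PGE2 set 1 and 5 without PGE2 set 2 at 1 h, 1 without ISO set 3 at 2 h, and at 4 h 1, 2 and 5 without ISO sets 1, 2 and 3 and 1 without PGE2 set 1. Calls that miss the threshold do not show equal responses. The intervals below cover genes called on the same values, which can enlarge the differences among them. Over the 105, 185 and 370 genes called for either ligand, the 95% interval of the difference had a median half-width of 0.32, 0.301 and 0.243 on the log2 scale, lay within 1 log2 unit for 92, 171 and 367 genes and excluded 0 for 16, 37 and 95. With the set number as a block the median half-width was 0.256, 0.226 and 0.193, and the interval lay within 1 log2 unit for 100, 176 and 367 genes and excluded 0 for 24, 72 and 115. The glycolysis list was lower with ISO than with PGE2 at 4 h at camera adjusted p = 0.0973, and 0.0343 with the block.

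**Figure D3:**
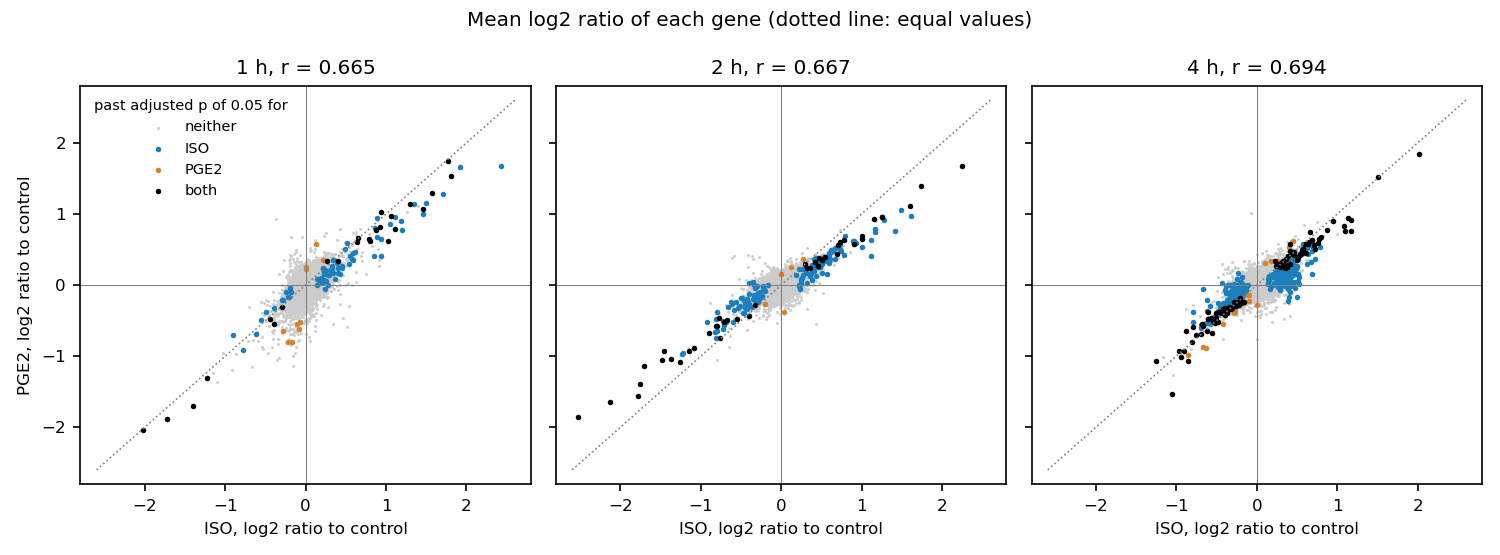
Log2 ratio against medium with PGE2 plotted over that with ISO at 1, 2 and 4 h, a point for each gene, with a dotted line at equal values. Pearson's r across genes was 0.665, 0.667 and 0.694.

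Cells given LPS together with ISO or PGE2 were first compared with medium. At 4 h Gbp2 was 28.0-fold higher with LPS plus ISO and 30.6-fold higher with LPS plus PGE2, Il1b at least 42.1-fold and 45.1-fold, with probes at the upper limit on 1 and 2 of 6 arrays, and Il6 36.8-fold (5.2 ± 0.11, SD, n = 3) and 47.6-fold (5.57 ± 0.50, SD, n = 3). Pax6 was 4.60-fold and 5.13-fold lower. Acod1 was listed at 0 on 6 of 6 arrays at 4 h with LPS alone and with each combination. Il10 was 3.39-fold higher at 1 h with LPS plus ISO and 2.84-fold higher with LPS plus PGE2. Nr4a1 was 14.4-fold higher at 1 h with LPS plus ISO (3.85 ± 0.30, SD, n = 3, adjusted p = 1.37e-10 in limma) and 10.6-fold with LPS plus PGE2 (3.41 ± 0.28, SD, n = 3). At 4 h 38 of 41 interferon-stimulated genes rose with LPS plus ISO (39 adjusted over the list alone, camera adjusted p = 7.93e-43) and 39 with LPS plus PGE2 (39 adjusted over the list alone, camera adjusted p = 7.21e-42). Of 23 G1 and S phase genes, 19 fell and 1 rose with each combination (19 and 1 adjusted over the list alone, camera adjusted p = 3.47e-11 and 1.1e-10). At 1 h 12 of 28 cAMP and CREB target genes rose and 1 fell with LPS plus ISO (14 and 1 adjusted over the list alone, camera adjusted p = 1.52e-10) and with LPS plus PGE2 (16 and 1 adjusted over the list alone, camera adjusted p = 5.8e-11).

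LPS plus ISO changed 781, 1457 and 3156 genes at 1, 2 and 4 h, and LPS plus PGE2 808, 1395 and 3327. The 1 h count for LPS plus ISO was 402 without set 1 and 400 without set 3, that for LPS plus PGE2 453 without set 1 and 374 without set 3, and the 2 h count for LPS plus ISO was 920 without set 3. The response differed between times for 1855 genes with LPS plus ISO and 1870 with LPS plus PGE2. With only the group itself in limma's fit, the counts at 1, 2 and 4 h were 1, 16 and 474 with LPS plus ISO and 0, 0 and 757 with LPS plus PGE2 (1398 and 1945 at an unadjusted p under 0.05 where 0 passed).

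LPS plus ISO was compared with LPS alone. The labels name 100 pM lipid binding protein for LPS alone and not for the combinations, so a difference between them cannot be assigned to ISO or PGE2 apart from this protein. At 1 h Nr4a1 was 5.34-fold higher with the combination (difference 2.42, SE 0.454, adjusted p = 0.0428 in limma, and 1.32e-06 with the set number as a block), and Plk2 was lower by a log2 difference of −1.75 (SE 0.3, adjusted p = 0.0193, and 0.000728 with the block). Plk2 was raised to 1.93 by LPS alone and stood at 0.17 with the combination. At 4 h Hivep3, which encodes a zinc-finger transcription factor, was 2.95-fold lower with the combination than with LPS alone, at 0.78 ± 0.21 against 2.35 ± 0.17 (SD, n = 3, adjusted p = 9.16e-05). Nes, the intermediate filament gene nestin, was 1.86-fold lower at −0.33 against 0.56 (adjusted p = 0.00225), and Dpys, a pyrimidine catabolic enzyme gene, stood at 0.33 against 1.30 (adjusted p = 0.00382). Slc37a2, a sugar phosphate transporter gene, was 1.63-fold higher at −0.92 against −1.63 (adjusted p = 0.00225). Each of these differences had the same direction in 3 of 3 sets. The naming rule asks for set values that do not overlap, so this follows from the choice of genes. In all, 2 genes differed at 1 h, 0 at 2 h and 10 at 4 h, 5 higher and 5 lower. At an unadjusted p under 0.05 there were 629, 308 and 351, where 526 would be reached by chance. This fit leaves out the pairing of sets by number. With the block the counts were 6, 16 and 53, and with only both groups in the fit limma called 0 at each time (234, 386 and 333 at an unadjusted p under 0.05).

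In the fit without a block, the calls between LPS plus ISO and LPS alone depended on single sets. Sets were not left out with the block, here or for LPS plus PGE2. At 1 h the count was 0 without LPS set 1, 2 or 3 or without LPS plus ISO set 1 or 3, and 1 without LPS plus ISO set 2. Nr4a1 was then at adjusted p = 0.319, 0.171, 0.0503, 0.324, 0.208 and 0.0992 in that order, and Plk2 at 0.319, 0.0569, 0.0503, 0.285 and 0.0828 in the first 5. At 2 h the count was 2 without LPS set 2 and 1 without LPS plus ISO set 2. At 4 h it was 6 without LPS set 2, 4 without LPS set 3 and 5 without LPS plus ISO set 1. Dpys was lost without LPS set 2 (adjusted p = 0.0573) and without LPS plus ISO set 1 (adjusted p = 0.0685), and Hivep3, Nes and Slc37a2 passed in each of these.

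Gene lists were compared in the same way between LPS plus ISO and LPS alone. The glycolysis and hypoxia list was lower with the combination at 4 h, with a median difference of −0.135 (camera adjusted p = 4.45e-06), with adjusted p = 0.204 with an estimated correlation. Of its 18 measured members 0 passed limma's threshold (4 lower adjusted over the list alone, 3 lower with the block), and 5 had an unadjusted p under 0.05. With the block the serum-responsive list was lower at 1 h (camera adjusted p = 0.275, 0.0352 with the block) and at 2 h (0.275 and 0.0167 with the block), and the G protein regulator list at 2 h (0.237 and 0.0259 with the block). The cytokine and chemokine list did not pass at 1, 2 or 4 h (camera adjusted p = 0.979, 0.899 and 0.537), and limma called 0 of their 26 members at each time, with 2, 1 and 1 at an unadjusted p under 0.05. The difference from LPS alone was −0.36 (SE 0.234) at 1 h, −0.28 at 2 h and 0.11 at 4 h for Tnf and 0.94 (SE 0.341), 0.20 and 0.12 for Il10, none past the threshold. With the block, Plk2 and Atf3 were lower with the combination at 2 h (differences −1.61 and −1.29, adjusted p = 0.0015 and 0.00779 with the block) and Edil3 was higher (1.45), and at 4 h Tgm2 was higher (1.03, adjusted p = 0.00441 with the block).

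LPS plus PGE2 was compared with LPS alone in the same way, with the same limit from the lipid binding protein. At 4 h Cp, which encodes the copper-binding protein ceruloplasmin, was 1.69-fold lower with LPS plus PGE2 than with LPS alone (0.80 against 1.56, SE of the difference 0.11, n = 3, adjusted p = 0.000933 in limma). Clec4n was 2.27-fold higher at 1.53 against 0.34 (adjusted p = 0.00579) and Hivep3 2.16-fold lower at 1.24 against 2.35 (adjusted p = 0.0171). All 3 had the same direction in 3 of 3 sets, which again follows from the naming rule. These 3 genes were the only ones called at 4 h, and limma called 0 at 1 h and 0 at 2 h. At an unadjusted p under 0.05 there were 484, 242 and 424 genes at 1, 2 and 4 h, where 526 would be reached by chance. This fit, too, leaves out the pairing of sets by number. With the set number as a block the counts were 3, 3 and 50, and with only both groups in the fit limma called 0 at each time (254, 288 and 394 at an unadjusted p under 0.05). With the block Nr4a1 was higher at 1 h (difference 1.97, adjusted p = 0.711 and 7.87e-05 with the block) and Plk2 lower (−1.48, adjusted p = 0.279 and 0.0126 with the block). At 4 h the block also called Ddit4, a stress-induced inhibitor of mTOR signalling, higher by 1.41, Tgm2 higher by 0.94, Vegfa higher by 0.75, Rgs2 lower (−1.16) and Cd180, which encodes a Toll-like receptor homologue, lower (−0.74). The genes called only with the block were named after their values were seen. The 4 h count was 6 without LPS set 1, 5 without LPS set 3, 9 without LPS plus PGE2 set 1 and 1 without LPS plus PGE2 set 3, and the 2 h count was 1 without LPS plus PGE2 set 2. Clec4n was lost without LPS plus PGE2 set 3 (adjusted p = 0.183), and Hivep3 without LPS set 1 (0.0574), LPS set 2 (0.139), LPS plus PGE2 set 2 (0.0909) and LPS plus PGE2 set 3 (0.185). No gene list passed for LPS plus PGE2 against LPS alone. The difference from LPS alone was −0.28 (SE 0.234), −0.11 and 0.10 at 1, 2 and 4 h for Tnf and 0.68 (SE 0.341), −0.31 and −0.08 for Il10, none past the threshold.

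**Figure D4:**
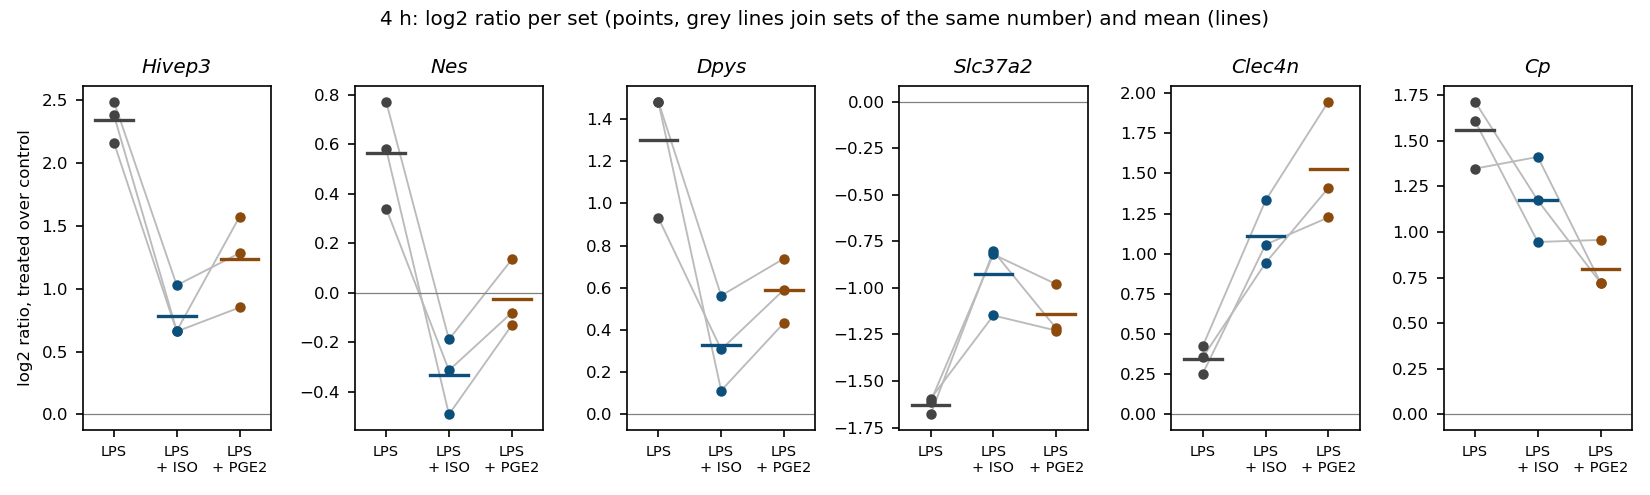
Log2 ratio against medium at 4 h for 6 genes in each set with LPS alone, LPS plus ISO and LPS plus PGE2, with grey lines joining sets of the same number. Hivep3 stands at 2.35 with LPS alone, 0.78 with LPS plus ISO and 1.24 with LPS plus PGE2, and Cp at 1.56 with LPS alone and 0.80 with LPS plus PGE2.

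The last comparison asked whether the combined response equalled the sum of the single responses on the log2 scale, with the same limit from the lipid binding protein, which the labels name for LPS alone and not for the combinations. Clec4e had log2 ratios of 2.37 with LPS and 1.17 with ISO at 4 h, which sum to 3.54, and 2.54 with both (F test in limma over the 3 times, adjusted p = 0.00999). Cnnm2 at 2 h had −0.04 with LPS, 1.01 with ISO and 0.17 with both (adjusted p = 9.68e-06). Cebpb at 1 h had 0.90, 1.03 and 1.06 (adjusted p = 0.0133), Igf1 at 4 h −0.39, −0.54 and −0.47 (adjusted p = 0.0101), and C5ar1 at 4 h 1.32, 0.95 and 1.44 (adjusted p = 0.00558). These 5 genes passed with each of the 27 sets left out in turn. For ISO 9 genes departed from the sum, 99 with the set number as a block, and the other 4 of the 9 were lost in 7, 13, 18 and 21 of the 27 fits. For PGE2 only Cnnm2 departed (adjusted p = 0.0389), and 15 genes did so with the block. It was lost in 18 of the 26 fits that left out a set, with an adjusted p of up to 0.245. The ISO count was 5 without LPS plus ISO set 2 at 2 h, without LPS set 1 or set 3 at 4 h, or without LPS plus ISO set 3 at 4 h, and 18 without ISO set 1 at 4 h.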

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

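Among the tests in this part, those of genes already at their limit through LPS were chosen after the result was seen.

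The response to LPS differed between times for 1943 genes, that to ISO for 62, that to LPS plus ISO for 1855 and that to LPS plus PGE2 for 1870, which singled these results out as differences of the same contrast between groups. In each case 1 of 100 splits of the 9 sets into 3 times, the real one, gave as many genes. The highest of the others gave 1878, 23, 1564 and 1059. A share of 1 in 100 argues against chance but does not exclude it. For LPS the margin was narrow, at 1943 against 1878. The response to PGE2 differed between times for 1 gene. No split was run for it because PGE2 had 2 sets at 1 h. Of the genes changed with LPS, 27 were higher at 1 h and lower at 4 h and 51 the reverse.

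Among 1987 probes outside the annotation with a measured value, 550 changed with LPS at 4 h, 246 higher and 304 lower. These probes were not part of the gene counts.

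Departures from the sum of single responses were called for 9 genes with ISO and 1 with PGE2 (99 and 15 with the set number as a block). Genes called for both ligands at one time were measured at another: the 43 picked at 2 h had at 4 h, in the direction of the ligand, an ISO response of 0.635 ± 0.124 without LPS and 0.289 ± 0.0543 with LPS (SD, n = 3) and kept shares of 0.455 for ISO and 0.681 for PGE2, and the 103 picked at 4 h kept 0.308 and 0.374 at 2 h, lower with LPS in 3 of 3 sets throughout. The highest share, 0.681, argues against a chance excess at the time used for picking. Slopes of the combination on LPS alone of at least 0.906 argue against compressed ratios. A share of at most 0.516 among genes that LPS left unchanged argues against a limit reached through LPS for ISO in those genes only. For genes that LPS moved, the test cannot decide, because it left them out. The genes were picked by their responses without LPS only, so a smaller share with LPS can follow from that choice. Kept values of 0 also draw a response toward 0. Neither of these was tested. For PGE2 such a limit cannot be told apart, because 10 such genes kept 0.869 at 4 h, lower in 2 of 3 sets, while 50 such genes kept 0.529 at 2 h, lower in 3 of 3 sets. A smaller effect of both ligands in LPS-treated cells may be biological and stays a hypothesis, and lipid binding protein, named in the labels for LPS alone only, stays open as untested.

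The 2 arrays of PGE2 at 2 h, set 1, had the lowest correlation of all pairs after turning, −0.585. Each array's deviation from the mean of the pair had an SD of 0.353 over probes against a median of 0.211 over all pairs. A wrong dye orientation on 1 array is argued against, because the mean of the pair followed the ISO response of sets 2 and 3 over 180 genes changed by ISO at r = 0.879 and their difference at 0.133. The difference followed the mean dye difference of the other 43 pairs at r = 0.685. Over all pairs this r was 0.374 to 0.801, with a median of 0.718. A dye effect that depends on the probe was thus seen in all pairs. Its r does not tell why this pair had the lowest correlation. No biological explanation was tested, since both arrays hold the same RNAs.

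ISO and PGE2 gave alike responses across genes, with a covariance of 0.016, 0.0119 and 0.0141 at 1, 2 and 4 h. Medium RNA shared by sets of the same number could raise it, and the covariance was 0.0281, 0.0157 and 0.019 over sets of the same number. Over sets of different numbers it was 0.00987, 0.00996 and 0.0117. The highest of 100 simulations with controls shared within a set number and no effect gave 0.00659, 0.00347 and 0.00393. That argues against controls shared by sets of the same number as the whole cause. Controls common to all sets of a time were not simulated and stay open. Part of the likeness may come from shared controls, and an effect common to both ligands, such as signalling through cyclic AMP, stays open as untested.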

How the results depend on the processing

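Of the alternatives in this part, centring on the median of values other than 0, including unlisted probes and keeping only genes measured on at least 44 arrays were chosen after the data were seen. Of 31 counts, those within 1.5 times the reported one numbered 31 with arrays centred on their median, which moves nothing, 31 with centring on values other than 0, 31 with robust eBayes, 28 with genes measured on at least 44 arrays, 27 with unlisted probes and those with several genes, 26 each with single probes, with probes measured on all 88 arrays and with zeros as missing, 20 with the block, 15 with a dye term and 7 with only the groups of the comparison. Background correction, a filter on dim probes and a slide block were not run, because the values hold no intensities, flags or slides, and signal over background is unknown. Unless a construction is named, the cause was not tested.

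With only the groups of the comparison in the fit, which leaves few degrees of freedom, the counts at 1, 2 and 4 h were 5, 131 and 1461 for LPS, 0, 0 and 0 for ISO and for PGE2, 1, 16 and 474 for LPS plus ISO, and 0, 0 and 757 for LPS plus PGE2. Against LPS alone, LPS plus ISO gave 0 at 1 and 4 h and LPS plus PGE2 0 at 4 h. Departures from additivity with ISO numbered 2, and differences between times 1053 for LPS, 0 for ISO, 0 for PGE2, 783 for LPS plus ISO and 885 for LPS plus PGE2. Unadjusted counts in limma for these zeros were 806, 1389 and 1340 for ISO, 460, 1031 and 1925 for PGE2, 1398 and 1945 for LPS plus PGE2 at 1 and 2 h, 234, 333 and 394 against LPS alone, and 1034 and 1511 between times. For the other zeros by limma given here they were 282 with single probes and 152 with genes on at least 44 arrays for additivity with PGE2, and 371 and 169 with probes measured on all 88 arrays for LPS plus ISO at 1 h and LPS plus PGE2 at 4 h.

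With all 88 arrays and a dye term the counts were 290, 352 and 598 for ISO, 165, 134 and 335 for PGE2 (57 higher and 108 lower at 1 h), 12 and 33 for LPS plus ISO against LPS alone at 2 and 4 h, 3, 3 and 24 for LPS plus PGE2 against LPS alone, 1 between ISO and PGE2 at 2 h, 79 and 14 for additivity, and 257 and 191 between times for ISO and PGE2. With the replicate block they were 78 for PGE2 at 1 h, 6, 16 and 53 for LPS plus ISO and 3, 3 and 50 for LPS plus PGE2 against LPS alone, 1 between ISO and PGE2 at 4 h, 99 and 15 for additivity, and 19 between times for PGE2. The block moved no other count by over 1.5 times. Of 1127 named gene values it ended 6 calls, added 9 and moved 6 uncalled values by more than their SD or SE.

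Smaller changes concerned the differences from LPS alone, additivity with PGE2 and PGE2 between times. Single probes gave 1, 1 and 17 for LPS plus ISO at 1, 2 and 4 h, 0 for additivity and 6 between times. Genes on at least 44 arrays gave 1 for LPS plus ISO at 2 h, 0 for additivity and 2 between times. Probes measured on all 88 arrays gave 0 and 4 for LPS plus ISO at 1 and 4 h, 0 for LPS plus PGE2 at 4 h, 2 for additivity and 8 between times. With unlisted probes and those with several genes the counts were 1 and 16 for LPS plus ISO at 1 and 4 h, 7 for LPS plus PGE2 at 4 h and 3 between times. With zeros as missing they were 1 for LPS plus ISO at 2 h, 1 and 9 for LPS plus PGE2 at 1 and 4 h, 2 for additivity and 2 between times.

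Leaving out 1 set at a time, with a lone remaining set assumed to vary like the other groups, gave at 1, 2 and 4 h 393 to 1342, 1077 to 1347 and 2543 to 2719 for LPS, 56 to 92, 92 to 138 and 211 to 262 for ISO, 15 to 26, 23 to 35 and 35 to 68 for PGE2, 400 to 884, 920 to 1264 and 2501 to 2887 for LPS plus ISO, and 374 to 848, 931 to 1185 and 2709 to 2939 for LPS plus PGE2. Against LPS alone the ranges were 0 to 1, 0 to 2 and 4 to 12 for LPS plus ISO and 0 to 0, 0 to 1 and 1 to 9 for LPS plus PGE2, and between ISO and PGE2 0 to 8, 0 to 1 and 0 to 5. Additivity gave 5 to 18 and 0 to 2, and differences between times 1513 to 1983 for LPS, 19 to 59 for ISO, 0 to 9 for PGE2, 1386 to 1857 for LPS plus ISO and 1399 to 1909 for LPS plus PGE2. Most of the sets behind these moves are named beside the results. Those behind the counts for additivity with PGE2 and the 12 for LPS plus ISO at 4 h are not. These fits had no block. Among named gene values, leaving out a set ended 539 calls, added 8 and left 2842 as they were, and no direction turned.

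Single probes turned the direction of 24 named values, ended 151 calls, added 2 and left 816 as they were. They moved 49 uncalled values by more than their SD or SE. A second probe of Csf3 stood at −0.167 and −0.28 with LPS at 1 and 4 h, −0.193, −0.252 and −0.464 with LPS plus ISO at 1, 2 and 4 h, and −0.218 and −0.404 with LPS plus PGE2 at 1 and 4 h. A probe of Ccl5 stood at −0.028 with LPS plus ISO at 1 h and 0 and −0.153 with LPS plus PGE2 at 1 and 2 h, Hmmr at 0.148, 0.116 and 0.164 with LPS, LPS plus ISO and LPS plus PGE2 at 1 h, Ifit3 at −0.465 and −0.137 with LPS and LPS plus PGE2 at 1 h, Ccl22 at −0.031 and −0.078 with LPS at 2 and 4 h, and Ccrl2 at −0.095 and −0.034 with LPS and LPS plus ISO at 1 h. Others were C5ar1 at −0.018 with ISO at 4 h, Cd4 at −0.03 with LPS at 1 h, Ccnd1 at 0.04 with LPS plus ISO at 1 h, Ndrg1 at −0.001 with LPS plus PGE2 at 2 h and Tnfrsf11a at 0.01 with LPS plus PGE2 at 4 h. Centring on values other than 0 ended 10 calls of named values and moved 5 uncalled values by more than their SD or SE. An estimated correlation ended 56 of 141 calls of gene lists, and the block ended 3 and added 10.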

Other observations

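No test in this part was chosen after the result was seen.

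Single genes of the cAMP pathway and the PGE2 receptors are given as values. Pde4b, a cAMP-degrading phosphodiesterase, was 5.33-fold higher with LPS at 1 h, 8.72-fold at 2 h (3.12 ± 0.31, SD, n = 3, adjusted p = 1.12e-08 in limma) and 6.49-fold at 4 h. Ptger2, which encodes the EP2 receptor for PGE2, had log2 ratios of 0.01, 0.69 and 1.54 ± 1.01 (SD, n = 3), and only the 4 h value passed (adjusted p = 0.000603, and 0.0613 without set 2). Ptger4 had −0.12, −0.16 and 0.22 with LPS and did not pass. With ISO alone Akap10, which anchors protein kinase A, was 1.64-fold lower at 2 h (adjusted p = 4.12e-05), and Pde8a, another cAMP phosphodiesterase, was 1.42-fold higher at 2 h and 1.43-fold higher at 4 h. Vegfa was 1.80-fold higher with LPS at 2 h (adjusted p = 0.000617) and at −0.06 at 4 h, which did not pass.

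Further lists are given as counts. Of 20 adhesion and matrix genes, 10 rose with LPS at 2 h (10 adjusted over the list alone, camera adjusted p = 3.96e-06). Of 21 oxidative stress genes, 6 rose at 1 h (6 adjusted over the list alone, camera adjusted p = 1e-04) and 8 rose and 1 fell at 2 h (8 and 1 adjusted over the list alone, camera adjusted p = 0.000113). Heat shock genes were shifted upward with PGE2 at 2 h (camera adjusted p = 0.00101, median log2 ratio 0.063). Of the 19 measured, limma called 0, with 2 adjusted over the list alone and 3 at an unadjusted p under 0.05.

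Chemokine genes with unequal probes are given as values. Ccl4 was 4.16-fold higher with LPS at 2 h as the mean of probes between 0 and 3.81, and Csf3, a granulocyte growth factor gene, 5.14-fold higher at 4 h from probes at −0.28 and 5.0.

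Splits of the samples were counted for the comparisons of groups of 3 sets. For each of 14 comparisons with medium only 4 turnings of the sign of the 3 sets exist, too few for a share under 0.05, and 1 turning, the real one, gave as many genes. The real count and the highest other were 997 and 57, 1671 and 0, and 3228 and 13 for LPS at 1, 2 and 4 h, 95 and 1, 180 and 0, and 353 and 4 for ISO, 48 and 0, and 120 and 0 for PGE2 at 2 and 4 h, 781 and 4, 1457 and 3, and 3156 and 0 for LPS plus ISO, and 808 and 0, 1395 and 20, and 3327 and 51 for LPS plus PGE2. The 10 splits of 6 sets are also too few. Against LPS alone at 1, 2 and 4 h, LPS plus ISO gave 2, 0 and 10 genes and at most 1, 0 and 6 in another split, and LPS plus PGE2 gave 0, 0 and 3 and at most 36, 11 and 17, and ISO against PGE2 gave 0 and 0 at 2 and 4 h and at most 1 and 0. The splits that gave 36, 11 and 17 genes point to a structure of the samples, in which sets of the same number lie together. Among splits that part all pairs of the same number the highest other was 0, 0 and 1 for LPS plus ISO and 1, 1 and 2 for LPS plus PGE2. With the set number as a block only splits that part all such pairs were counted, which are fewer than 10 and too few for a share under 0.05. The real counts with the block were 6, 16 and 53 against at most 1, 1 and 1, and 3, 3 and 50 against at most 1, 1 and 3. Splits as large as the real one, itself included, numbered 1, 10 and 1 for LPS plus ISO, 10, 10 and 4 for LPS plus PGE2, and 10 and 10 for ISO against PGE2 at 2 and 4 h. Each value of 10 belongs to a real count of 0, which every split reaches, so it carries no information.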
